A study of Zea mays with 6 samples.

How the data were processed

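Total RNA from leaf 3 of maize line A661 was compared between a section without chlorophyll (CL, distal) and a section with chlorophyll (CC, proximal), with 3 biological replicates of each, per the labels' protocols. Plants were kept in a growth chamber under fluorescent light of 228 µmol m-2 s-1 with 14 h of light and 10 h of dark, and 250 ng of RNA were biotin-labelled for a 3' expression array, per the labels' protocols. Labelling from the 3' end reads the last part of a transcript, so probe sets of a gene can differ where transcripts end at different places.

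The deposited values are RMA expression values on a log2 scale, and RMA, Affymetrix Expression Console and limma are named in the submitters' processing notes. Versions of these tools are not given in the sources used here. RMA subtracts background, applies quantile normalization across arrays and summarises the probes of a set, which compresses differences at the dim end. The deposited table held 17555 probe sets for 6 arrays with no missing value, and no scanner file was used here, so no probe could be tested against background. Samples were grouped by the leaf section in their labels. No sample was left out, and 0 columns of values per sample were unused.

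Probe sets were named through an older platform annotation, with symbols updated by gene ID from a RefSeq table. There were 1452 probe sets with 1 gene, 1 with several genes, from which no gene was named, and 16102 with no gene named here. The named ones covered 1108 genes, of which 1060 were found in the RefSeq table, 981 had a name that was not a locus number, gene model or map marker, and 222 had more than 1 probe set. A gene was represented by its probe set with the highest mean; in 1 of the 222 genes probe sets passed in both directions.

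The main test was limma's linear model with empirical Bayes (limma 3.58.1 in R 4.3.3), CL minus CC, without a block and with no filter. Benjamini-Hochberg adjustment ran over all probe sets for counts of probe sets and over all genes for genes, with a threshold of 0.05. Changes are log2 differences, SE is the moderated standard error and n is 3 per section. A permutation test of single genes in a design of 3 against 3 cannot give a p under 0.1, so the limma model, which shares the spread across genes, carries the tests.

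A set of 26 gene lists was fixed before the data were examined, as were the alternatives and the rule for named genes. Lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 and adjustment over the 24 lists with at least 3 genes; the light signalling list had 2 genes and the photorespiration list had 0, so neither was tested. The lists were written as patterns for symbols and gene descriptions, and no descriptions were used here, so members were matched by symbol and synonym and 245 genes fell in at least 1 list. Some members therefore share a symbol with the list's theme and not its function. A version of each list leaves out members judged from their names to be such and adds clearly named ones. It was written from the names alone, after the annotation had been read and before any gene's value was looked at. A member left out may still share the list's function.

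Named genes were, among genes with an informative name, the 6 largest rises and 6 largest falls that passed 0.05 with all CL arrays on one side of all CC arrays, the 3 members with the largest change among those past 0.05 over all genes in each called list, and the member with the smallest p of each other list. Further members named as examples, and genes of the cell wall, defence, carbon and other lists outside this rule, were chosen after their values were seen.

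The fit was tested on simulated data with 17555 probe sets, 200 of them changed, in 5 runs. It recovered 30% of changes of 0.5, 75.6% of changes of 1, 92.8% of changes of 2 and 99.6% of changes of 3 on the log2 scale, and called a mean of 7.6 unchanged probe sets per run. The simulated noise was independent between probe sets and few of them were changed, whereas 31.1% passed in the data. These shares therefore need not hold for the data. Array pairs of a section were checked for duplicates: the SD of their log2 differences was 0.251 to 0.387.

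The alternatives were a block for the replicate number, an intensity trend or robust variance in the empirical Bayes step, centring on array medians, a further quantile normalization, leaving out the dimmest 25% or 50% of probe sets, the mean of a gene's probe sets, array weights, an adjusted p of 0.01, each array left out in turn, an estimated correlation in camera, the fry test and the lists checked by name. Neither scaling alternative turned the sign of any called probe set (0 with median centring, 0 with quantile normalization).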

Results

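Leaf transcripts of the maize inbred line A661 were measured on 6 single-colour Affymetrix maize arrays. Plants grew at 15 °C for 3 weeks and at 25 °C for 1 further week, after which leaf 3 carried a distal section without chlorophyll (CL) and a proximal section with chlorophyll (CC). The 2 cm of either section that bordered the transition were sampled in 3 biological replicates per section, with CC as the control. Each array gave log2 values for 17555 probe sets, of which 1452 could be paired with a single gene, covering 1108 genes. Array medians lay between 6.29 and 6.36, and the 25th percentile was 3.95 to 3.97 on the CL arrays and 4.04 to 4.15 on the CC arrays. Pearson correlations over probe sets were 0.989 to 0.995 within a section and 0.963 to 0.982 between sections. The first principal component held 71.9% of the variance and placed the CL arrays at -40.8 to -24.6 and the CC arrays at 22.1 to 48.0, with replicate 1 of each section nearest the other section. The section without chlorophyll was the distal one on all 6 arrays, so chlorophyll content and position along the leaf cannot be told apart, and the number of arrays limits the precision. All 6 arrays share the 15 °C and 25 °C periods. Any difference between the sections in the temperature during their growth therefore cannot be told apart from position or chlorophyll either.

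The comparison of CL with CC asked which transcripts differed between leaf tissue with and without chlorophyll. The largest rise in CL among genes with an informative name was that of asn1 (NCBI gene 542435), an asparagine synthetase, at 10.59 ± 0.29 in CL and 5.36 ± 1.72 in CC (SD, n = 3 each), a 37.7-fold difference. Its log2 change was 5.24 (SE 0.77), and 6.23 without CC replicate 1. Next came wip1 (NCBI gene 542729), a wound-induced proteinase inhibitor, with a log2 change (CL minus CC) of 4.14 (SE 0.76), and aox3 (NCBI gene 542676), a mitochondrial alternative oxidase, with 3.30 (SE 0.57). The CC arrays of wip1 read 7.43, 8.32 and 5.10, so the size of its change depends on single arrays. The cytosolic glyceraldehyde-3-phosphate dehydrogenase gene gpc4 (NCBI gene 100037774) rose by 3.22 (SE 0.27), sip1 (NCBI gene 542299) by 3.06 (SE 0.34) and the pyruvate decarboxylase gene pdc3 (NCBI gene 541919) by 2.99 (SE 0.10). These 6 rises had limma adjusted p between 1.13e-05 and 0.00635. A second probe set of asn1 had a log2 change of 0.30 and did not pass, and the mean of both probe sets gave 2.77.

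The largest fall in CL was that of umi11 (NCBI gene 606488), which also carries the name cyclotide, from 8.81 ± 0.74 in CC to 3.44 ± 0.58 in CL (SD, n = 3 each), a log2 change of -5.36 (SE 0.42). The acid invertase gene ivr2 (NCBI gene 542324) fell by 3.64 (SE 0.78), GT1 (NCBI gene 542140) changed by -2.76 (SE 0.43) and the alpha-expansin gene expa1 (NCBI gene 541904) by -2.71 (SE 0.13). On the CC arrays ivr2 spread from 6.35 to 9.42, so the size of its change depends on single arrays. The gene glk1 (NCBI gene 541882), a Golden2-like transcription factor that promotes chloroplast development, fell by 2.43 (SE 0.29), and the cytokinin oxidase gene cko3 (NCBI gene 542056) changed by -2.40 (SE 0.21). These 6 falls had limma adjusted p between 9.92e-05 and 0.0109. Mean values of umi11, expa1 and ivr2 in CL lay at the 16.7th, 21.9th and 27.8th percentile of all probe sets, that of aox3 in CC at the 27.6th and that of asn1 in CC at the 40.3rd, with 2 of its 3 CC arrays at 4.20 and 4.52, so these differences reach into the dim end of the arrays.

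**Figure D1:**
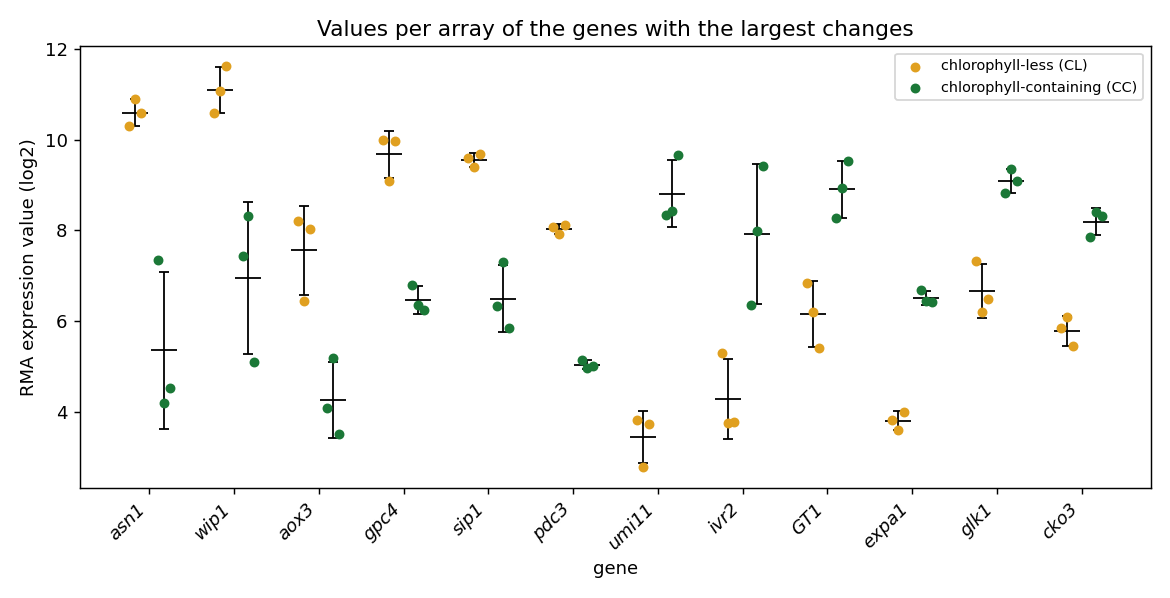
Log2 expression values on each array for the 6 named genes with the largest rise and the 6 with the largest fall in CL; points are arrays, the horizontal bar is the mean of a section and the whiskers are 1 SD (n = 3). The genes were chosen among those with the 3 CL arrays on one side of the 3 CC arrays, so none overlaps. In CC asn1 has an SD of 1.72 and pdc3 one of 0.10.

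Across the arrays, 2789 probe sets rose and 2668 fell in CL at a limma adjusted p under 0.05, together 31.1% of the 17555 tested. At least 2-fold changes were found for 546 probe sets higher and 449 lower in CL, and 850 of these 995 had no gene named here. Among the 1108 genes, 218 rose and 247 fell, together 42.0%. That share is the one to set beside the counts of called list members below. The sections' values did not overlap in 618 of all 1108 genes (55.8%), a state that chance gives 10% of genes in a design of 3 against 3. The counts without a fold limit moved by over 1.5 times when 1 array was left out. Without CL replicate 3 they were 1308 higher and 1082 lower, without CC replicate 2 they were 1663 and 1371, without CL replicate 2 1840 and 1484, and without CC replicate 3 1821 and 1669. Gene counts moved that far without CL replicate 3, to 129 higher and 132 lower, and for the genes lower in CL also without CC replicate 2, to 156.

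Of 9 photosystem and antenna genes, 6 fell, 0 rose and 3 did not pass (6 falls and 0 rises adjusted over the list alone). The photosystem I subunit gene psad1 fell from 11.86 ± 0.26 to 10.12 ± 0.39 (SD, n = 3 each; limma adjusted p = 0.00168), whereas lhcb5, an antenna protein gene of photosystem II, changed by -0.58 (SE 0.13) and OEE3, which encodes the oxygen-evolving protein PsbQ, by -0.44 (SE 0.10). The list was lower than other genes with a camera adjusted p of 0.0297, and adjusted p = 0.754 with an estimated correlation. That p was 0.0653 without CC replicate 1, 0.0559 without CC replicate 2 and 0.0567 after a further quantile normalization.

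Of 20 photosystem and carbon fixation genes, 15 lay at the bright end of the arrays, with a mean of 12 or more. Of 11 genes matched to the C4 and Calvin cycle list, 1 rose and 2 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.769). The rubisco activase gene rca1 fell by 0.32 (SE 0.08), with an adjusted p of 0.0231. Its adjusted p lay between 0.0511 and 0.0628 when CL replicate 2, CL replicate 3, CC replicate 1, CC replicate 2 or CC replicate 3 was left out, and was 0.0554 after a further quantile normalization. The other fall was that of rcalm (log2 change -0.28), which the list checked by name leaves out. The gene that rose, pdlk1 (log2 change 0.56), encodes by its name a kinase and not an enzyme of the cycle. The phosphoenolpyruvate carboxylase gene pep1 (log2 change 0.05, SE 0.08), the pyruvate phosphate dikinase gene pdk1 (0.05, SE 0.08), the NADP-malic enzyme gene me3 (0.03, SE 0.07) and the rubisco small subunit gene rbcs1 (-0.08, SE 0.08) did not pass. Of 4 genes matched by symbol to the electron transport list, the ferredoxin gene FDX6 fell by 1.03 (SE 0.18) and fdx3 rose by 0.36. Their symbols do not show whether these ferredoxins serve photosynthesis, and both stay in the list checked by name. Adjusted over the list alone 1 rose and 2 fell, and the camera adjusted p was 0.769. Checked by name the list had 8 genes, of which 1 rose and 5 fell (camera adjusted p = 0.125), among them ftr1 at -0.54 and L-FNRI at -0.52.

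Pigment synthesis genes were few on the annotated part of the array. Of 5 genes matched to the chlorophyll synthesis list, 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.769). The member named for an enzyme of the pathway was oy1, a subunit of magnesium chelatase, which fell by 0.67 (SE 0.11, limma adjusted p = 0.0046). The member with the smallest p, por1, rose by 1.27 (SE 0.12) but encodes a porin, and por2 (log2 change -0.31) carries the name of an aquaporin; the remaining fall was por (-0.57). Of 9 carotenoid and plastid isoprenoid genes, BCH2, a carotene hydroxylase by name, rose by 1.36 and dxr, an enzyme of the plastid isoprenoid pathway, fell by 0.56; hdr10, which rose by 0.79 (SE 0.10), also carries the name hir1 and does not belong to the pathway. That list had 2 rises and 1 fall, the same adjusted over the list alone, and a camera adjusted p of 0.769.

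Genes for the plastid's own machinery moved both ways. Of 13 genes on the plastid expression and import list, 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.197). The 4 falls were sigma factors of the plastid RNA polymerase: sig3 at -0.54 (SE 0.08), sig6 at -0.42, sig1 at -0.39 and sig2B at -0.37. The import receptor genes toc34 and toc35 rose by 1.02 (SE 0.18) and 1.21 (SE 0.19), and the other 4 rises were rps genes shared with the cytosolic ribosome list. Checked by name, without those, the list had 19 genes, of which 2 rose and 4 fell (camera adjusted p = 0.667). Both members of the light signalling list, glk1 and GLK13, fell, GLK13 with a log2 change of -1.58 (SE 0.36), also adjusted over the list alone; with 2 genes the list was not tested as a set.

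Cell wall and cytoskeleton genes mostly fell in CL. Of 35 genes on the cell wall growth list, 23 fell and 1 rose (25 and 1 adjusted over the list alone), and 10 fell by at least 2-fold. Alongside expa1, the cellulose synthase gene cesa2 fell from 8.25 ± 0.56 to 5.93 ± 0.14 (SD, n = 3 each), the beta-expansin gene expB6 changed by -2.24 (SE 0.19) and the tubulin gene tub3 by -1.68 (SE 0.11). The member that rose was expA4, by 0.46. As a set the list had a camera adjusted p of 4.54e-06, and adjusted p = 0.690 with an estimated correlation. Of 15 genes matched to the cell division list, 4 rose and 2 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.786); the cyclin genes cycD2 (0.73) and cycD1 (-0.50) moved apart, cdc2 (0.39), magi81248 (0.51) and CDC5 (0.51) rose, and umi11 is a member by the word cyclotide alone. The list's median of -0.06 and mean of -0.29 were negative while its test pointed up.

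The 3 genes matched to the respiration list were all alternative oxidases, which pass electrons to oxygen past the later complexes of the chain, and all 3 rose (3 adjusted over the list alone): aox3, aox1 with NCBI gene 542074 by 2.09 (SE 0.30), and aox1 with NCBI gene 542073 by 0.64 (SE 0.09). The camera adjusted p was 0.0255, and adjusted p = 0.690 with an estimated correlation; with the uncoupling protein gene PUMP added from its name it was 0.121. Of 10 heat shock and chaperone genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone). The small heat shock protein gene hsp22 rose from 9.53 ± 0.62 to 11.37 ± 0.28 and CPN60I, a chaperonin of mitochondria, from 7.61 ± 0.29 to 9.44 ± 0.24 (SD, n = 3 each), while hsfb, a heat shock factor, rose by 0.49 (SE 0.09), hsp70-4 by 0.46 and hsp70-5 by 0.32. For that list the camera adjusted p was 0.00738, and adjusted p = 0.690 with an estimated correlation.

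Of 11 cytosolic ribosomal protein genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). The changes were led by csu36b(rpL19) at 1.09 (SE 0.18), rpl30 at 1.07 (SE 0.17) and RPL10 at 0.62 (SE 0.08). As a set they had a camera adjusted p of 0.000169, and adjusted p = 0.690 with an estimated correlation.

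Defence genes included several of the strongest rises without a call for the list. Of 8 genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone). Besides wip1 and sip1, the pathogenesis-related genes pr5 and prp4 rose by 2.09 (SE 0.48) and 2.01 (SE 0.35). The chitinase gene chn1 rose by 1.40 (SE 0.22), while prp2 fell by 0.41. The list checked by name leaves out sip1, which also carries the name Zlp. That choice does not show that sip1 lacks a role in defence. With a camera adjusted p of 0.0505 the list did not pass, nor did the list of 5 genes checked by name (0.112). The former p was 0.0128 without CC replicate 2 and 0.0241 without CC replicate 3. Of 31 glutathione S-transferase genes, which conjugate glutathione to toxic compounds, 11 rose and 7 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.142, and 0.0401 without CL replicate 2). Rises of at least 2-fold were found for 6 of them, led by gst42 at 2.86 (SE 0.38), gst7 at 2.07 (SE 0.33) and gst24 at 1.86 (SE 0.24), against 0 falls of that size; the smallest p of the list was that of gst2 at 1.67 (SE 0.12).

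Of 7 antioxidant genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.619), namely the catalase gene CAT3 at 0.67 and the superoxide dismutase gene Sod4A at 0.36 (SE 0.09, limma adjusted p = 0.0157, and 0.0661 without CL replicate 3). Of 8 cold, drought and abscisic acid genes, DBP1a rose by 0.56 and dbf2, a DREB-type factor, fell by 0.64 (SE 0.11); the counts were the same adjusted over the list alone and the camera adjusted p was 0.819. Of 11 jasmonate and ethylene genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.769). The rises were opr1 at 2.27 (SE 0.35) and the allene oxide synthase gene aos1 at 0.97, and the falls aoc1 at -0.68 and opr7 at -0.46. Of 5 genes matched to the senescence list, 0 rose and 2 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.197): see2a with a log2 change of -0.79 and mpao1 with -1.28 (SE 0.19), which is a polyamine oxidase and not an enzyme of chlorophyll breakdown. Of 6 phenylpropanoid and flavonoid genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.769), with the flavanone hydroxylase gene fht1 at -1.86 (SE 0.19) and BM1 at -0.93 against the chalcone synthase gene chs1 at 0.77 and a2 at 0.59.

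Carbon and nitrogen metabolism showed large changes of single genes. Of 25 sucrose and starch genes, 2 rose and 9 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.197). Beside ivr2, the ADP-glucose pyrophosphorylase gene agpsl1 fell from 11.14 ± 0.10 to 10.38 ± 0.21 (SD, n = 3 each) and the sucrose phosphate synthase gene sps1 changed by -0.80, while the cell wall invertase gene incw1 rose by 1.84 (SE 0.31) and TPS4, a member by symbol alone that the list checked by name leaves out, by 1.22. The falls of TPS9 and eks1 were likewise matched by symbol alone; checked by name the list had 2 rises and 13 falls among 31 genes and a camera adjusted p of 0.119. Of 10 nitrogen assimilation genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.742). Besides the rise of asn1, NNR1, a nitrate reductase gene, fell by 2.24 (SE 0.53). Also by name nitrate reductases, NR (log2 change -0.01) and nar (-0.81), which the list checked by name adds, did not pass. The gene gln1, which also carries the name gs2 of the plastid glutamine synthetase, fell by 1.01 (SE 0.09). The nitrate transporter gene Nrt1.1 changed by -0.72 and gln2 by 0.67. The list's median was -0.13 and its mean 0.13, and the test pointed down.

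**Figure D2:**
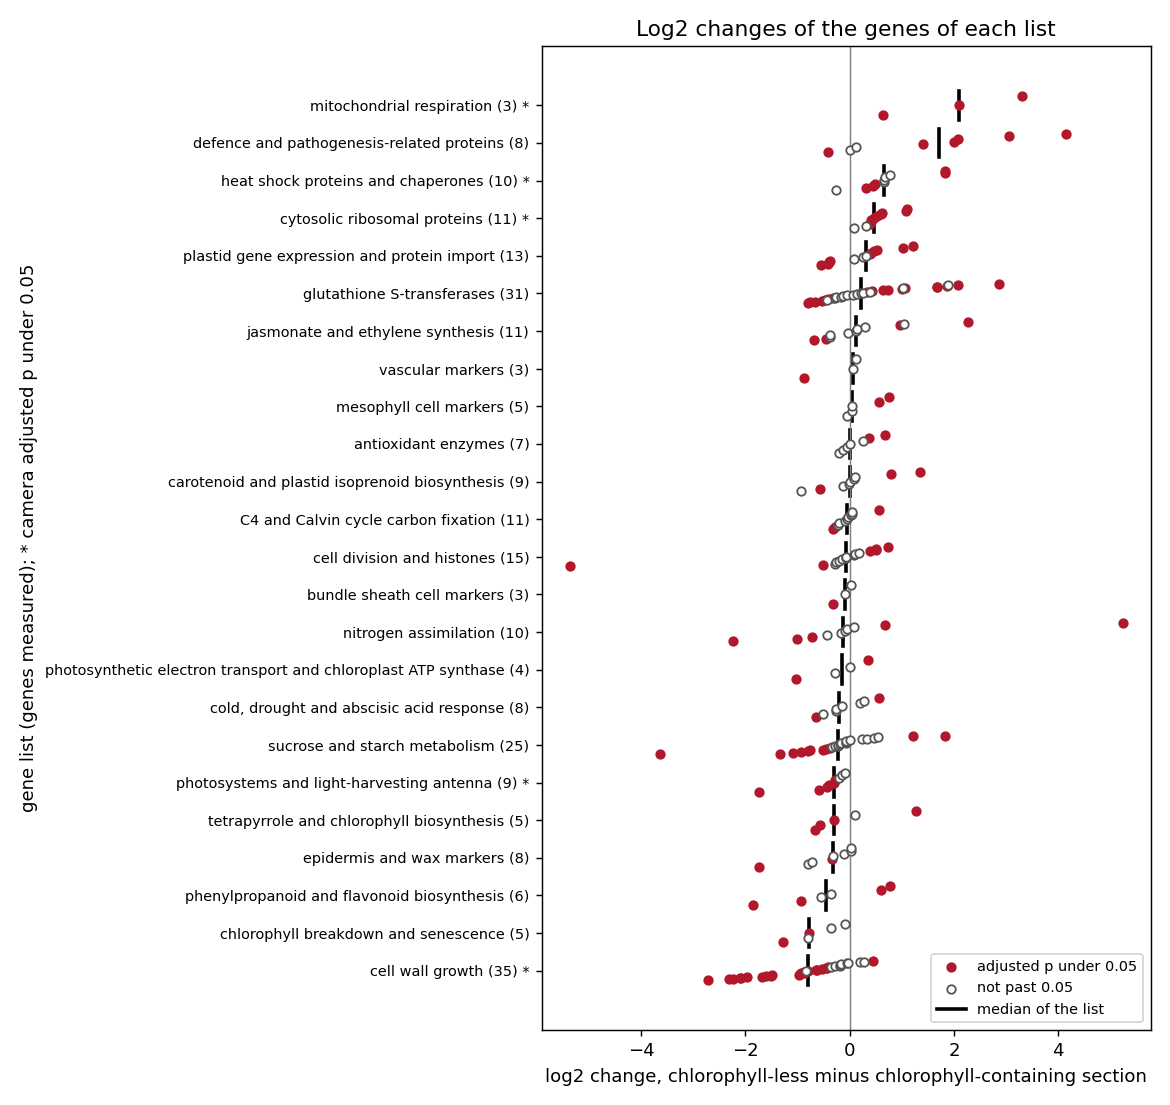
Log2 change (CL minus CC) of each gene in the 24 lists with at least 3 measured genes, ordered by the list's median; filled points passed a limma adjusted p of 0.05, open points did not, and black bars are medians. The cell wall growth list has a median of -0.80 with 23 of 35 genes falling, and the mitochondrial respiration list a median of 2.09 over 3 genes; asterisks mark the 5 lists with a camera adjusted p under 0.05.

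Markers of the leaf's cell types gave no list-wide call. Of 5 mesophyll markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.274): pdlk1 and ppt1, a phosphoenolpyruvate transporter of plastids, which rose by 0.75 (SE 0.12). Of 3 bundle sheath markers, rca1 fell, me3 and rbcs1 did not pass and the count was the same adjusted over the list alone (camera adjusted p = 0.769). Of 8 epidermis and wax markers, gl1, a wax synthesis gene, fell by 1.73 (SE 0.20) and gl15 changed by -0.33, also adjusted over the list alone (camera adjusted p = 0.288). Of 3 vascular markers, the sucrose transporter gene sut1 fell by 0.87 (SE 0.22, limma adjusted p = 0.0203), also adjusted over the list alone. The other members, PP2C (0.07) and pp2c-1 (0.13), did not pass and were matched by symbol alone, so sut1 is the 1 marker left when checked by name. The adjusted p of sut1 was 0.0612 without CL replicate 2, 0.0713 without CL replicate 3, 0.064 without CC replicate 2 and 0.0637 without CC replicate 3. The vascular list had a camera adjusted p of 0.902, a median of 0.07 and a mean of -0.22, with a test that pointed down; the median is that of PP2C, and the negative mean comes from sut1.

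Camera compares a list with the other genes, and of the 5 calls it made with a preset correlation of 0.01, 0 held with a correlation estimated from the data. That estimate rests on 4 residual degrees of freedom, and no list of the 24 tested had a camera adjusted p under 0.690 with it. It may have too little power to keep any call, so the lost calls do not show that the lists are unchanged. When the 6 arrays were split into 3 and 3 in the 10 possible ways, 2 splits gave 5 called lists, the real one included. The other splits mix the sections and keep part of their difference, so they do not measure chance alone.

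Checked by name, other lists also gained or lost members. The cytosolic ribosome list then had 15 rises and 0 falls in 18 genes, the heat shock list 8 and 0 in 13, the cell wall list 1 and 23 in 36, and the light signalling list 0 and 3 in 4 (camera adjusted p = 0.112). The carbon fixation list had 0 rises and 1 fall in 9 genes, the carotenoid list 1 and 1 in 9, the senescence list 0 and 1 in 4, the cell division list 3 and 1 in 13 and the mesophyll list 1 and 0 in 4. The nitrogen list had 2 rises and 4 falls in 13 genes, the cold list 1 and 2 in 11 and the phenylpropanoid list 2 and 2 in 7.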

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

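Each list version checked by name is an alternative chosen after the annotation had been seen; the other settings were fixed before the data were examined. For the 41 named genes, 593 results under alternatives had the same direction and side of the threshold, 15 no longer passed and 0 turned. Those 15 belong to 4 genes, whose adjusted p over all alternatives ranged from 0.00853 to 0.0827 (rca1), 0.00103 to 0.0726 (sut1), 0.00236 to 0.0733 (Sod4A) and 0.00151 to 0.0553 (OEE3). For the 24 tested lists 371 alternatives gave the same direction and side of the threshold, 34 did not, and 8 of those turned. No probe set was called in opposite directions by any setting. With no scanner data used here, how far a dim value lies above background is unknown, which limits values near the 25th percentile. Where a cause is not named below, the cause was not tested.

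The labels do not say whether sections of the same number came from the same plants, and no positive correlation paired them. Deviations of same-numbered arrays correlated at -0.54, -0.35 and -0.39, and 0 of 6 arrays matched best with their own number. With the number as a block, which leaves fewer residual degrees of freedom, 1020 probe sets were higher and 850 lower, with 126 genes higher and 128 lower, and the defence list had an adjusted p of 0.0384. The block moved no other count by over 1.5 times and changed no other list's call; OEE3, rca1, Sod4A and sut1 lost theirs.

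At an adjusted p of 0.01, a stricter limit by construction, 1126 probe sets were higher and 867 lower, and 121 genes were higher and 106 lower. Array weights gave 4388 and 4940 probe sets and 372 genes lower. Without the dimmest 50% of probe sets, which leaves fewer to test, 1656 were lower, 298 of them by at least 2-fold.

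With 1 array left out, 1308 to 2818 probe sets were higher and 1082 to 2865 lower. At least 2-fold changes were 412 to 688 higher and 350 to 565 lower, and genes 129 to 202 higher and 132 to 247 lower. CL replicate 3 gave the lowest count in each but the 2-fold falls, for which CL replicate 2 did. Counts moved by over 1.5 times without CL replicate 3, without CL replicate 2 (1840 higher, 1484 lower), without CC replicate 2 (1663, 1371, and 156 genes lower) and without CC replicate 3 (1821, 1669). Adjusted p ranged from 0.0146 to 0.0653 for photosystems and antenna, 0.0128 to 0.103 for defence, 0.0401 to 0.214 for glutathione S-transferases, 0.695 to 0.902 for cold, drought and abscisic acid and 0.572 to 0.964 for jasmonate and ethylene. It crossed 0.05 for photosystems without CC replicate 1 (0.0653) or 2 (0.0559), for defence without CC replicate 2 (0.0128) or 3 (0.0241) and for the transferases without CL replicate 2 (0.0401). The cold list turned upward without CC replicate 3 (0.879) and the jasmonate list downward without CC replicate 1 (0.964).

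An estimated correlation ended all 5 list calls: adjusted p = 0.754 for photosystems and antenna and 0.690 for cell wall growth, cytosolic ribosomal proteins, heat shock proteins and mitochondrial respiration. With 4 residual degrees of freedom this setting passed none of the tested lists, so its power may be too low to judge them. The respiration call also ended with the list checked by name (0.121), and the photosystem call with a further quantile normalization (0.0567). Over all alternatives adjusted p started at 0.00586 for photosystems, 7.24e-09 for cell wall growth, 1.36e-06 for ribosomal proteins, 0.000464 for heat shock proteins and 0.00901 for respiration, and ended at the values with an estimated correlation. For defence it was 0.0128 to 0.752 and for the transferases 0.0254 to 0.754.

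The defence list passed with median centring (0.0301), a further quantile normalization (0.0353), an intensity trend (0.0409), the mean of a gene's probe sets (0.0418) and without the dimmest 50% of probe sets (0.0254), as did glutathione S-transferases in the last setting (0.0254). Checked by name, with sip1 left out, the defence list did not pass (0.112), and whether sip1 belongs on the list is not settled. Without those dim probe sets, the cold list (0.832), the jasmonate list (0.922) and the phenylpropanoid list (0.832) turned, as did bundle sheath markers with quantile normalization (0.996) and cell division with array weights (0.983) and with fry (0.756). Fry, which asks whether a list's genes move one way and not whether they differ from other genes, passed antioxidant enzymes (0.0427), bundle sheath (0.018) and mesophyll markers (0.029), defence (0.0279), nitrogen assimilation (0.00924), plastid expression (0.0342) and sucrose and starch (0.029).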

Other observations

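The gene families in the next 2 paragraphs were grouped by name after the results had been seen, and the test of dividing cells and the splits of single lists were chosen then too. Of 12 families, the 6 described with values are those with a camera adjusted p under 0.05; genes whose changes prompted the grouping, such as pdc3, gpc4 and CPN60I, count in those tests, so they are no independent evidence, and 0 of the 6 passed with an estimated correlation (adjusted p = 0.368 to 0.630 with an estimated correlation). Aquaporins, the water channels of plasma membrane and vacuole, were mostly lower in CL: of 25 genes 15 fell and 1 rose (16 and 1 adjusted over the list alone), led by the silicon channel gene Lsi1 at -2.01 (SE 0.20), pip1e at -1.92 (SE 0.27) and pip2d at -1.46 (SE 0.19), while PIP1-3 rose by 0.51. Of 13 genes of mitochondrial carriers, porins, prohibitins and chaperonins, 7 rose and 2 fell (7 and 2 adjusted over the list alone): besides CPN60I, CPN60II rose by 1.96 (SE 0.23), the prohibitin gene phb4 by 1.61 (SE 0.21) and the porin gene vdac2 by 1.46 (SE 0.11), while vdac1b fell by 0.55 and PUMP changed by -0.38.

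Of 13 genes of fermentation and glycolysis, 6 rose and 0 fell (7 and 3 adjusted over the list alone). The 6 were pdc3, gpc4, the pyruvate decarboxylase gene pdc2 at 2.20 (SE 0.27), gpc3 at 1.56 (SE 0.14), gpc2 and GAPC; the alcohol dehydrogenase genes adh1 (-0.57, SE 0.20) and adh2 (-0.90, SE 0.32) did not pass. Of 50 chromatin genes, 17 rose and 1 fell (15 and 1 adjusted over the list alone), among them the nucleosome assembly genes nfa101 at 1.18 (SE 0.15) and nfa103 at 0.97 (SE 0.12), against nfd101 at -1.15. The other 32 did not pass, so the share called was not above the 42.0% of all genes. Of 12 translation factors 6 rose and 0 fell (6 and 1 adjusted over the list alone), and of 11 protein disulfide isomerases 5 rose and 0 fell, namely pdi, pdi3, pdi4, pdi6 and pdi8 (5 and 0 adjusted over the list alone). The others were the cytokinin, seed storage, MADS-box, Rop GTPase, origin recognition and membrane transport families.

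Of 35 cell wall growth genes 23 fell and 1 rose in CL, and a smaller share of dividing cells in the CL section would predict lower cell division transcripts too. The 13 cell division genes checked by name had a median log2 change of -0.0602 (bootstrap 95% interval -0.20 to 0.17), above the -0.5 set as the bound. As a set these genes thus did not fall as far as that bound, which was chosen after the results had been seen. The interval resampled genes and not samples, and 9 of the 13 did not pass. Whether these genes track dividing cells in this tissue was not tested, so fewer dividing cells stay possible as a source. Another candidate explanation that stays open is position along the leaf, since the CL section was always the older, distal one: 0 arrays hold a distal section with chlorophyll or a proximal one without. A loss of chlorophyll as such is as open, as is the temperature at which each section grew, and none of these was tested.

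For tissue without chlorophyll, photosystem and carbon fixation transcripts showed small differences, with a median log2 change of -0.21 over 20 genes, which include pdlk1 and rcalm, matched by symbol alone, and psad1 at -1.74. Bright probe sets may saturate: 15 of these genes had a mean of 12 or more, and the SD of changes over the other 157 probe sets that bright was 0.34 against 0.57 over 2444 with a mean of 9 to 11, a ratio of 0.599. That lies between the bounds set for and against saturation, so some compression could hide part of a fall. The 15 bright genes had a median of -0.20 and the 5 dimmer ones -0.23, but those 5 ranged from psad1 at -1.74 to pdlk1 at 0.56, so the medians decide nothing. The same transcripts measured by a method without an upper limit of signal would tell a real small change from a compressed one.

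Arrays of a section differed from each other along the axis that separates the sections: CC replicate 1 and CL replicate 1 lay nearest the other section. Over probe sets, CC3 minus CC1 correlated with CC2 minus the CL mean at 0.393, and a further quantile normalization left 0.385. The further step did change calls elsewhere, and 4541 of the 5457 called probe sets kept theirs in the same direction. As RMA had already applied quantile normalization, a scaling effect left in the values may also outlast a further one. The test therefore cannot decide on array scaling. Tissue of the other section in CC replicate 1 would give it an equal share of the CL level in both directions. The median share was 0.175 at 688 probe sets higher in CL and 0.346 at 565 lower in CL. Their difference was -0.172 (bootstrap 95% interval -0.20 to -0.14). The probe sets were chosen by the contrast with CC2 and CC3, which also served as the reference. That choice alone can make the shares unequal, and the bootstrap resampled probe sets of 1 array, so admixture stays undecided. A graded state of the leaf across the transition, so that samples of a section may differ in how far it had gone, stays open and was not tested.

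With 10 splits of the 6 arrays no share can fall under 0.1. The real split gave the most called probe sets and genes, 1 of 10 splits each time: 2789 higher and 2668 lower, 546 and 449 by at least 2-fold, and 218 and 247 genes, where the highest other split gave 0 throughout; at an unadjusted p under 0.05 limma found 7825 probe sets in the real split and at most 1495 in another. Lists behaved otherwise: 2 of 10 splits, the real one included, gave 5 called lists, the highest other number. The real adjusted p was the smallest for cytosolic ribosomal proteins (0.000169, the smallest of the others 0.000409) and mitochondrial respiration (0.0255 and 0.0573). It was as small in 2 of 10 splits for photosystems and antenna (0.0297 and 0.00575) and for heat shock proteins (0.00738 and 0.000152), and in 3 of 10 for cell wall growth (4.54e-06 and 6.18e-07). Camera with its preset correlation thus also called 4 of these 5 lists in splits that mix the sections. Each such split sets 2 arrays of one section and 1 of the other against the reverse. Part of the section difference therefore stays in the contrast, and the rest adds to the spread. Neither the list calls nor the 0 called probe sets of these splits show what chance alone would give.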
